A study of Homo sapiens with 6 samples.

How the data were processed

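Messenger RNA was measured by sequencing in 6 libraries of the human endometrial adenocarcinoma line Ishikawa, 3 from cells transfected with a miR-1229-5p mimic and 3 from cells transfected with a negative control mimic. Groups and replicate numbers came from the library titles and the transfection label. Per the labels' protocols, mRNA was enriched with oligo-dT, fragmented, reverse transcribed and sequenced on a NovaSeq X Plus. The same protocol speaks of tissue samples, although the label gives a cell line. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

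The authors deposited estimated counts per gene, not scaled between libraries, in 1 table of 62703 rows. The submitters' processing notes name hg38, RSEM and DESeq2, without versions or roles. The aligner and the annotation release are not given in the sources used here. Of the rows, 20966 carry no gene symbol but do carry a gene identifier. They held 1.25% to 1.49% of the counts of a library and stayed in the tests. The authors also deposited a mean of the estimated counts for each group, which equals the mean of the 3 libraries to within 3.3e-05 and was not used further.

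Estimated counts were rounded to whole numbers before any test. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17034 genes tested and 45669 not tested. Libraries were scaled by TMM, with factors from 0.981 to 1.022. The mimic was compared with the control by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust) without covariates, and p was adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. The fitted biological coefficient of variation was 8.6%. CPM values are counts scaled to the library total after TMM scaling, given as mean and SD of 3 libraries. Standard errors (SE) of log2 fold changes came from the same fit. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.53 to 10.79 between pairs, so none was counted as a repeat of another.

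Of 26 gene lists fixed before the data were examined, 25 had at least 5 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01), with camera using an estimated correlation, and with fry. These p-values were adjusted over the lists. Terms and pathways annotated in the deposited table with 10 to 500 tested members were tested among called genes by a one-sided Fisher's exact test against the 15367 tested genes that carry a term, with adjustment over 3147 terms in both directions.

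Sites were searched in the 3' UTR of 1 coding transcript per gene of GENCODE release 29 (GRCh38), which matched 58279 of the deposited identifiers (92.9%). A tested gene had to have a 3' UTR of at least 30 bases, which left 13083 genes. Coordinates below are from that annotation, 1-based. The authors' own release is not known. The sequence of miR-1229-5p, GTGGGTAGGGTTTGGGGGAGAGCG, was taken from general knowledge and matched the start of the MIR1229 hairpin in the reference. The site of its bases 2 to 8 is CTACCCA (7mer-m8), an 8mer is that site followed by A, a 7mer-A1 pairs bases 2 to 7 and is followed by A, and a 6mer pairs bases 2 to 7. The difference of median log2 fold change between genes with a 7mer-m8 or 8mer and genes without a 6mer was ranked among 2639 other 7-mers of equal G+C and CpG count. A scan of all 7-mers found in at least 30 genes used fold changes limited to 2 in size on the log2 scale, before and after a quadratic correction for 3' UTR length, GC content and expression, and a further correction took in the number of GGGG. The sequences of the duplexes used for transfection are not given in the sources used here.

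Named genes followed a rule fixed at the same time as the lists. It took STMN1, CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, ZEB2, TWIST1 and the MIR1229 host gene MGAT4B. It added the 10 called genes with the largest change in each direction (at least 1 CPM in the higher group, no overlap between groups, no pseudogene, clone or antisense name), up to 4 called members of each list by p, the 5 largest of the lower genes with an 8mer site, and the 5 smallest p in each direction. The code for pseudogene names at first left out genes such as MMP14 and EMP1. This was noticed after values had been seen, and the annotation's gene type was then used with the rule unchanged. DGCR8, DNAJC3, DYNC1H1, FKBP4, HSP90AA1, HSPB1, HSPD1, IER2, INSIG1, IRF1, RAC1 and ROCK2, and members of enriched terms, were named after their values were seen. Some genes that the rule takes are not reported here.

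The scripts were tested on counts simulated from the means and sizes of these libraries for the mimic against the control. An earlier version used 1 simulated data set, which gave a higher share of false calls, and 5 were then drawn. Over those 5 data sets, edgeR recovered 46% of genes changed 1.3-fold, 67.6% at 1.5-fold, 81.6% at 2-fold and 96.4% at 4-fold, with 250 simulated changes of each size. The same genes were changed in each data set. They were drawn only from genes above a minimum mean count, so recovery may be lower for genes of few counts. False calls made up 7.5% of its calls, above the nominal 5%, with at most 16 in 1 data set. With no gene changed it made 6 calls in the 5 data sets. An implanted list passed camera with 0 of 24 other lists, and an implanted 7-mer was found as the lowest.

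Alternatives chosen in advance were RLE and upper-quartile scaling, no low-count filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a test against a 1.2-fold change, other definitions of a site, and leaving out each library in turn. Thinning all libraries to 15390951 counts was added after the data were seen. Where the text says that a library was left out, its group has 2 libraries in that fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the site tests, term tests and plots.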

Results

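Gene expression was compared between Ishikawa cells, a human endometrial adenocarcinoma line, carrying a mimic of the microRNA miR-1229-5p (3 libraries) and the same line carrying a negative control mimic (3 libraries). A mimic is a synthetic RNA duplex made to act as the microRNA. The question was which genes change downstream of miR-1229-5p, and the title of the series names STMN1 and the epithelial-mesenchymal transition (EMT). The mimic libraries held 24266852, 15390998 and 15719325 estimated counts, and the control libraries held 17497992, 16902685 and 19568817. Mitochondrially encoded genes took 6.91% ± 0.69 (SD, n = 3) of the counts with the mimic and 7.30% ± 0.89 (SD, n = 3) with the control. Libraries from oligo-dT-enriched mRNA do not measure the mature microRNA, so its level after transfection was not checked.

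STMN1, which encodes the microtubule-destabilizing protein stathmin, fell 1.77-fold with the mimic, from 249 ± 3.80 CPM (SD, n = 3) to 140.4 ± 8.14 CPM (SD, n = 3). Its log2 fold change was -0.83 (SE 0.07, edgeR adjusted p = 1.3e-06). STMN1 (ENSG00000117632) lies on chromosome 1 at 25884181 to 25906991 (GRCh38, minus strand). CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548), which encodes the epithelial adhesion protein E-cadherin, fell 1.66-fold, from 212 ± 6.27 to 128 ± 5.29 CPM (SD, n = 3), with a log2 fold change of -0.73 (SE 0.07, edgeR adjusted p = 4.36e-06). Both genes kept the call in every alternative fit run for single genes and with each library left out.

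The mesenchymal cadherin gene CDH2 did not pass the test, with a log2 fold change of -0.27 (SE 0.12, edgeR adjusted p = 0.183), nor did the fibronectin gene FN1 at -0.27 (SE 0.09, adjusted p = 0.0901). Among genes of EMT transcription factors, ZEB1 stood at -0.26 (adjusted p = 0.279), TWIST1 at 0.35 (adjusted p = 0.2) and SNAI1 at 0.01 (adjusted p = 0.988) on the log2 scale by edgeR, none of them past the threshold. The intermediate filament gene VIM had 3 counts in each mimic library and 0 in each control, and the transcription factor genes SNAI2 and ZEB2 had at most 4 and 3 counts in a library. These 3 genes fell below the low-count filter and were not tested. MGAT4B, the gene whose locus holds MIR1229, stood at 0.15 (adjusted p = 0.216). Of the whole list of 15 measured mesenchymal and EMT markers, 0 were called higher and 1, TNC, was called lower (camera adjusted p = 0.12; 3 lower when adjusted over the list alone). CDH1 was the 1 called member, lower, among 24 epithelial markers (camera adjusted p = 0.886; 1 lower when adjusted over the list alone).

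**Figure D1:**
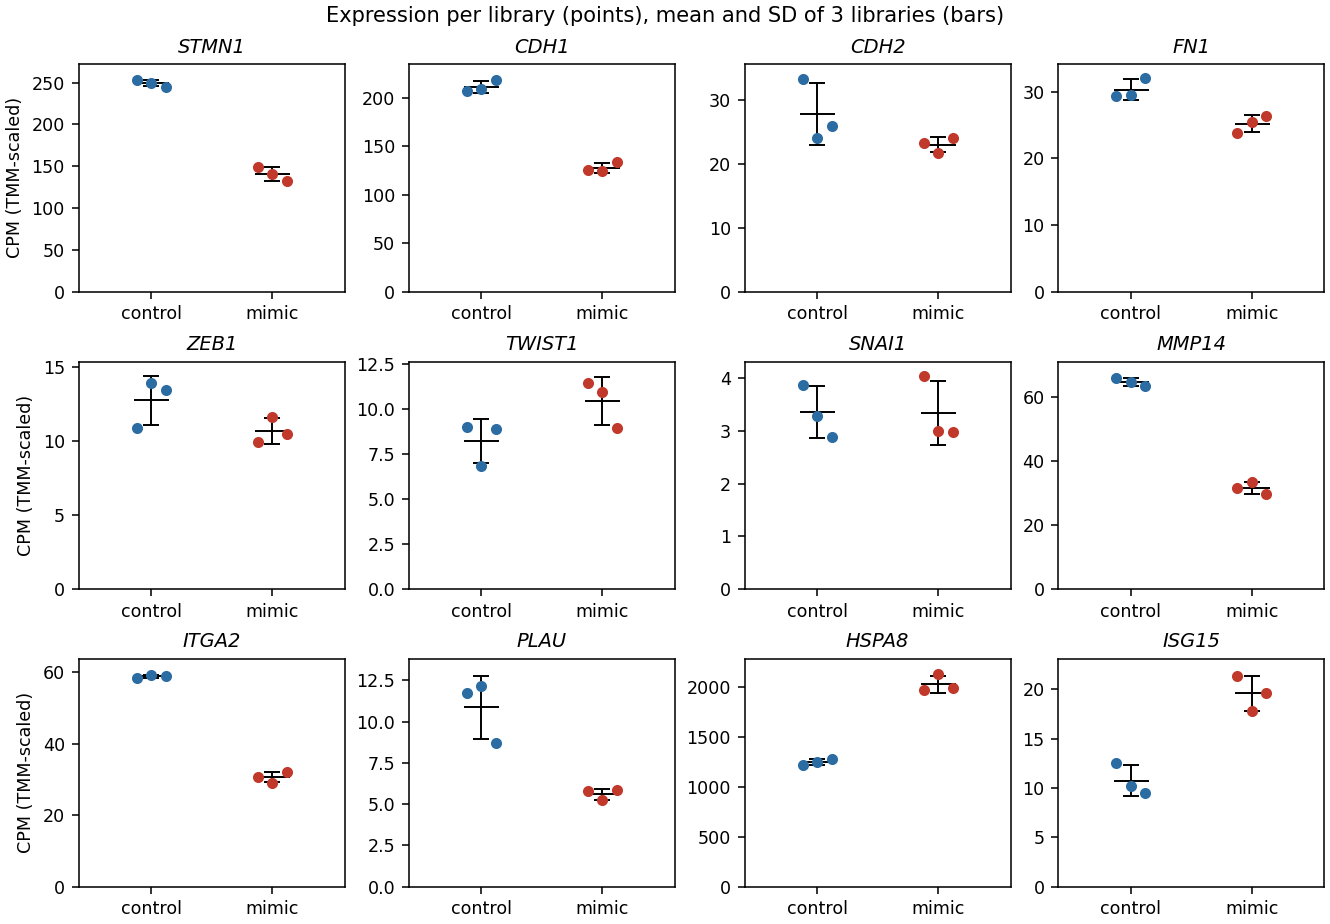
Expression of 12 genes in each library as TMM-scaled CPM on a linear axis from 0, with the control in blue and the mimic in red, points for libraries and black bars for the mean and SD of 3. STMN1, CDH1, MMP14, ITGA2 and PLAU were called lower with the mimic and HSPA8 and ISG15 higher, while CDH2, FN1, ZEB1, TWIST1 and SNAI1 did not pass the test.

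Across 17034 tested genes, 1081 were called, 584 higher and 497 lower with the mimic. Most changes were small: the median fold was 1.34 among the higher and 1.31 among the lower genes, and 41 genes changed at least 2-fold, 23 higher and 18 lower. The smallest p belonged to SLC6A6, the taurine transporter gene, which fell 2.26-fold (log2 fold change -1.17, SE 0.07, edgeR adjusted p = 3.05e-08) from 242 ± 7.37 to 107 ± 2.01 CPM (SD, n = 3). MMP14, the gene of a membrane-anchored matrix metalloprotease, fell 2.05-fold (log2 fold change -1.04, SE 0.08, edgeR adjusted p = 4.53e-07). ITGA2, STMN1 and DYNLL2, a dynein light chain gene (log2 fold change -0.77), followed by p. Among the higher genes, TOMM22 of the mitochondrial import complex rose 2.54-fold, EMC6 of the endoplasmic reticulum membrane complex 2.59-fold, the tropomyosin gene TPM4 2.73-fold, the palmitoyltransferase gene ZDHHC16 2.52-fold and ZCCHC3 2.17-fold, with edgeR adjusted p from 8.03e-08 to 6.86e-07.

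By size, the other large decreases on the log2 scale were PCDHA11 (-2.11), FGFBP3 (-1.33), ENDOU (-1.21), HHLA1 (-1.12), GM2A (-1.06), ADGRB1 (-0.99), EMP1 (-0.99) and B3GLCT (-0.97). The other large increases were ZNF625-ZNF20 (2.75), ANKRD31 (1.59), LRRC26 (1.53), C17orf67 (1.51), TMEM100 (1.46) and PARP12 (1.37), with means of at most 2.93 CPM in the mimic. These 6 increases, and the decreases of PCDHA11, FGFBP3, HHLA1 and ADGRB1, lost the call in 1 or more fits with a library left out. PCDHA11 shares exons with other protocadherin alpha genes and ZNF625-ZNF20 is a read-through of a pair of genes, so both values are uncertain. The number of called genes fell to 707 without mimic 3, to 410 without control 2 and to 534 without control 3. It was 165 in a test against a 1.2-fold change.

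**Figure D2:**
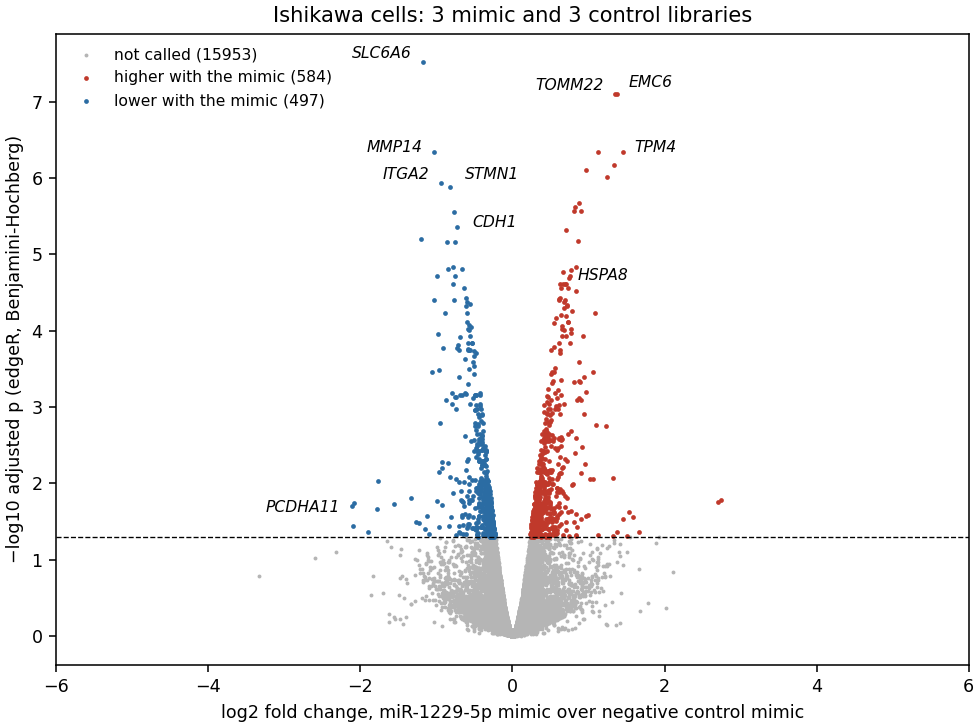
Log2 fold change of the mimic over the control (horizontal) against -log10 of the edgeR adjusted p (vertical) for 17034 genes, with the dashed line at an adjusted p of 0.05. The 584 genes called higher (red) and 497 called lower (blue) mostly lie within a 2-fold change, and SLC6A6 has the smallest p.

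Genes of the extracellular matrix, proteases and integrins had the smallest camera p of the 25 lists tested. Of 30 measured members, 11 fell and 0 rose (19 fell when adjusted over the list alone), 29 had a negative log2 fold change, and the median was -0.28. The list's adjusted p was 4.33e-17 by camera, 0.102 by camera with an estimated correlation and 0.0122 by fry. The members that fell included MMP14, the collagen-binding integrin gene ITGA2 (1.92-fold, log2 fold change -0.94, SE 0.08), the urokinase gene PLAU (1.93-fold, log2 fold change -0.95, SE 0.16) and the hyaluronan receptor gene CD44 (1.35-fold, log2 fold change -0.43, SE 0.08). Among pathways annotated in the deposited table, focal adhesion was the most enriched by p among the lower genes, with 17 of 143 members called (one-sided Fisher's exact test, adjusted p = 0.0144).

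Heat shock chaperone genes were higher as a list, with 8 of 16 members called higher, 0 lower and a median of 0.29 on the log2 scale (9 higher when adjusted over the list alone). The list's adjusted p was 2.3e-09 by camera, 0.339 by camera with an estimated correlation and 0.0224 by fry. HSPA8, a constitutive HSP70 gene, rose 1.62-fold from 1252 ± 32.7 to 2033 ± 85.2 CPM (SD, n = 3), and DNAJA1 and DNAJB1, genes of its co-chaperones, rose by 0.43 and 0.37 on the log2 scale. HSP90AA1, HSPB1, HSPD1 and FKBP4 rose by 0.27 to 0.37 on that scale. HSPA1B rose by 0.78, lost the call without mimic 1 (adjusted p = 0.0703), and shares reads with the near-identical HSPA1A, so its value is uncertain. In the list of the unfolded protein and integrated stress response, 2 of 28 members rose, TRIB3 and CHAC1, and 3 fell, HSPA5, SLC7A11 and DNAJC3 (camera adjusted p = 0.535; 3 higher and 7 lower over the list alone). HSPA5, which encodes BiP, a chaperone of the endoplasmic reticulum, fell by 0.58 on the log2 scale.

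Of 20 measured genes of the microRNA machinery, 5 fell and 0 rose: DDX6 (log2 fold change -0.66), AGO4 (-0.55), TNRC6A (-0.36), TENT2 (-0.35) and DGCR8 (-0.29), with the same counts when adjusted over the list alone. The list's adjusted p was 0.00167 by camera, 0.37 with an estimated correlation and 0.023 by fry. Among 33 microtubule and cytoskeleton regulators, 5 fell (STMN1, CDC42, ROCK1, ROCK2 and DYNC1H1) and 2 rose (TUBA1C and RAC1), with a camera adjusted p of 0.319 (4 higher and 6 lower over the list alone). STMN1 is in that list because the study's title names it and is not independent evidence, and TUBA1C shares reads with other alpha tubulin genes. Of 29 interferon and double-stranded RNA response genes, 4 rose, namely IFI6 (log2 fold change 0.95), ISG15 (0.87), IFI44L (0.83) and IFIT1 (0.71), and 1, IRF1, fell (adjusted p = 0.0621 by camera, 0.37 by camera with an estimated correlation and 0.019 by fry; 6 higher and 1 lower over the list alone). IFI44L lost its call without mimic 2, control 1 or control 2 and with libraries thinned to equal depth. The interferon list passed without control 1 (adjusted p = 0.0386) or control 3 (adjusted p = 0.0382).

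Cytosolic ribosomal protein genes had 35 of 36 positive log2 fold changes around a median of 0.105, with 2 called higher (RPL13 and RPS2) and 0 lower (1 higher over the list alone). Both have many processed pseudogenes, so their counts are uncertain. The adjusted p was 0.000259 by camera, 0.926 with an estimated correlation, 0.55 by fry and, by camera, 0.0577 without mimic 1, and ribosomal protein genes took 5.52% ± 0.45 (SD, n = 3) of the counts with the mimic and 5.02% ± 0.09 (SD, n = 3) with the control. In the cholesterol and sterol synthesis list, 4 of 25 genes fell, among them HMGCS1, MSMO1 and DHCR7, and 1, INSIG1, rose (2 higher and 4 lower over the list alone). Its adjusted p was 0.0292 by camera, 0.779 with an estimated correlation and 0.278 by fry. By camera without mimic 2, mimic 3 or control 1 it was 0.0957, 0.149 and 0.189, and in limma-voom 0.0535. Of 13 fatty acid synthesis genes, SCD and ELOVL5 fell and ME1 rose (camera adjusted p = 0.274; 1 higher and 4 lower over the list alone).

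The remaining lists did not pass camera. Called members included CDK6 and RRM2 higher and CCND1 lower of 32 genes of G1/S and DNA replication (adjusted p = 0.472), and HMMR higher of 32 genes of G2/M and mitosis (adjusted p = 0.873). XPC rose and FAS and TNFRSF10B fell among 24 p53 targets (adjusted p = 0.535). The signalling feedback genes DUSP4, DUSP5, DUSP6 and SPRY4 fell and IER2 rose among 23 MAPK and immediate early genes (adjusted p = 0.326). CCND1 and CD44 fell among 16 Wnt targets (adjusted p = 0.137), TGFB2 fell among 22 TGF-beta targets (adjusted p = 0.558), and TNFAIP3 and ICAM1 fell among 19 genes of NF-kB and inflammatory cytokines (adjusted p = 0.426). CA12 rose and CCND1 fell among 18 estrogen and progesterone response genes (adjusted p = 0.472). PFKL and CA12 rose and SLC2A1 and HK2 fell among 29 genes of glycolysis and hypoxia (adjusted p = 0.535). SDHB and CYC1 were among the called genes, all higher, of 30 nuclear genes of oxidative phosphorylation (adjusted p = 0.131), with 4 higher over the list alone. The 15 mitochondrially encoded genes (median -0.12 on the log2 scale, adjusted p = 0.134) and 11 replication-dependent histone genes (median 0.20, adjusted p = 0.269 by camera, 0.0259 by fry) had 0 calls. Markers of cells not named in the labels had 0 calls as well, with 5 measured for fibroblast and stromal cells (adjusted p = 0.873), 7 for endothelial cells (adjusted p = 0.873) and 4 for immune cells, too few to test.

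Adjusted over the list alone, the counts for those lists were 3 higher and 3 lower for G1/S, 1 higher for G2/M, 1 higher and 2 lower for p53 targets, 2 higher and 4 lower for MAPK, 2 lower for Wnt targets, 2 higher and 2 lower for TGF-beta targets, 2 lower for NF-kB, 1 higher and 1 lower for estrogen response, and 4 higher and 2 lower for glycolysis. The histone, mitochondrial, fibroblast, endothelial and immune lists again had 0. The sign of the median and of the mean differed for the epithelial, unfolded protein response and fibroblast lists, whose camera tests pointed down without passing. No list passed camera with an estimated correlation, where the lowest adjusted p was 0.102.

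**Figure D3:**
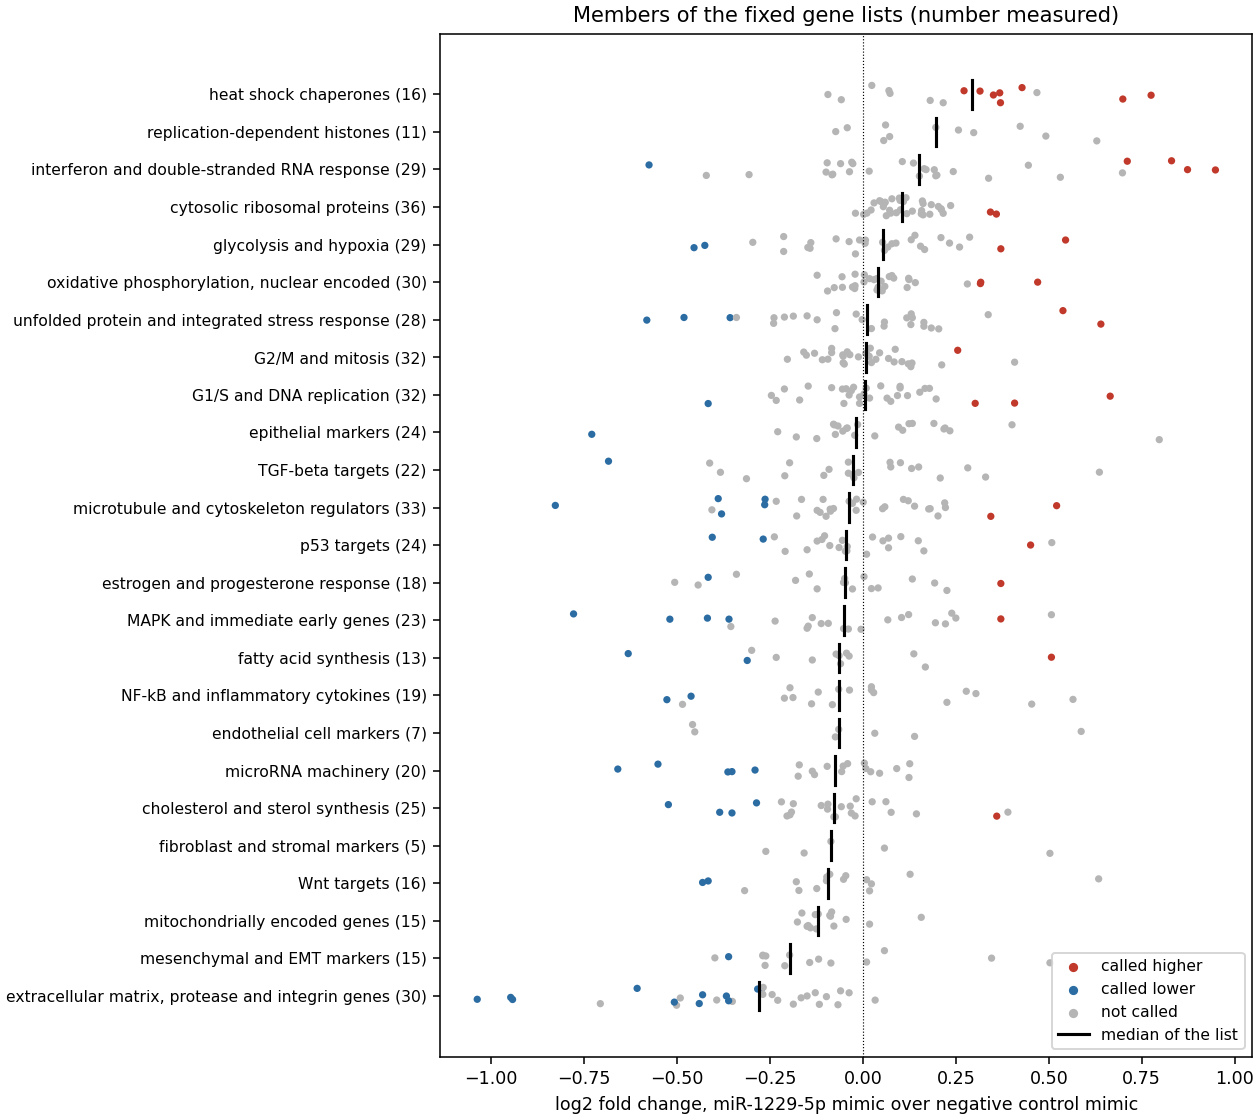
Log2 fold change of the mimic over the control (horizontal) for every measured member of the 25 tested lists (rows, number measured in brackets), with called genes in red (higher) or blue (lower), other genes in gray and black bars for list medians. Medians run from 0.29 for heat shock chaperones to -0.28 for extracellular matrix, protease and integrin genes.

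Among all annotated terms, 5 passed the one-sided Fisher's exact test. Lower genes were enriched in focal adhesion, in proteoglycans in cancer (16 of 145 members, adjusted p = 0.0249), with CD44, PLAU and TGFB2, and in lamellipodium membrane (6 of 21 members, adjusted p = 0.0407), with CD44, VASP and EPHA2. Higher genes were enriched in mitochondrial inner membrane (33 of 387 members, adjusted p = 0.024), with CYCS and NDUFA8, and in heat shock protein binding (9 of 44 members, adjusted p = 0.0407), with HSPA1B and FKBP4. Without control 1 or control 2, 0 terms passed (387 and 332 at an unadjusted p under 0.05), while 35 passed without mimic 1, 12 without mimic 2 and 31 with the calls of DESeq2.

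Genes with a seed site of miR-1229-5p in the 3' UTR were slightly lower than genes without one. The median log2 fold change was -0.03 in 1030 genes with a 7mer-m8 or 8mer site and 0.02 in 9871 genes without a 6mer, a difference of -0.047. That difference lay at percentile 6.71 of 2639 composition-matched 7-mers, and between 1.55 and 19.02 with a library left out. Camera, which compares the genes with a site to the others, gave p = 0.0525, and p = 0.0618 with an estimated correlation, while fry, which unlike camera asks only whether the genes with a site moved one way, gave p = 0.0241. After correction for 3' UTR length, GC content and expression the difference was -0.017, at percentile 2.73. Of the 254 genes with an 8mer, 10 were called lower and 3 higher (3.9% and 1.2%), against 3.0% and 4.5% of genes without a site. For 7mer-m8, 7mer-A1 and 6mer genes these shares were 5.3% and 3.7%, 5.0% and 2.9%, and 4.8% and 3.9%. The share called lower was thus not largest for 8mers. The lower genes with an 8mer that changed most were BPNT2 (log2 fold change -0.84, site on chromosome 8 at 56962707 to 56962714), WLS (-0.75), SLC2A1 (-0.45), TRPM7 (-0.43) and CCND1 (-0.42).

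For miR-1229-5p, the longest site in the 3' UTR of STMN1 was a 7mer-A1, on chromosome 1 at 25900462 to 25900468, and the longest in CDH1 was a 7mer-A1 on chromosome 16 at 68833757 to 68833763. Both 3' UTRs also held the 8mer GGGGAGAA, at 25900841 to 25900848 and at 68833859 to 68833866, which pairs with the strand complementary to miR-1229-5p. Of the genes named above with a miR-1229-5p 8mer, TRPM7 also held GGGGAGAA and BPNT2 held 2 sites GGGGAGA. CCND1 held only the 6mer of that strand, and WLS and SLC2A1 held none of its sites.

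**Figure D4:**
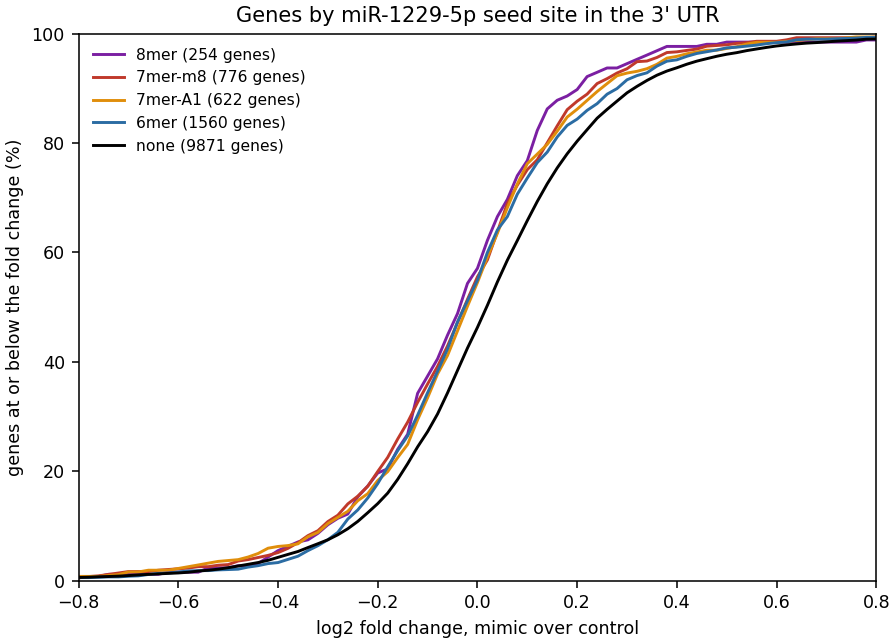
Cumulative share of genes (vertical, percent) at or below each log2 fold change of the mimic over the control (horizontal), by the longest miR-1229-5p site in the 3' UTR. Medians were -0.04 for 254 genes with an 8mer, -0.03 for 776 with a 7mer-m8, -0.02 for 622 with a 7mer-A1, -0.03 for 1560 with a 6mer and 0.02 for 9871 with none.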

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

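Thinning all libraries to equal depth was chosen after seeing the data, and the other settings before. Of the values given for called genes, 0 changed direction in any setting, and 0 of the 1081 calls had another sign in any fit. Called genes, 1081 in the edgeR test, numbered 165 in the test against a 1.2-fold change (94 higher, 71 lower) and 410 to 916 with a library left out (220 to 484 higher, 190 to 480 lower). Without control 2, 399 of the 1081 were called again, and 505 without control 3. Fewer libraries were tested there, and thinning to equal depth gave 968. Genes changed at least 2-fold, 41, numbered 106 without a low-count filter, which admits genes of few counts, 18 in DESeq2 and 30 to 52 with a library left out. Of 81 named genes called, 29 were also called in the test against a 1.2-fold change. Over the other settings run for single genes (up to 14), 48 kept the call in all, 33 lost it in 1 or more, and 24 of these lost it only with a library left out. Without control 2, 28 of the 33 lost it, and without control 3, 22. Besides those said above to lose it, these included CA12, CCND1, CHAC1, CYC1, DHCR7, DUSP4, DUSP5, ELOVL5, FAS, HMMR, ICAM1, MSMO1, RPL13, RPS2, SCD, SDHB, TENT2, TNC, TNFAIP3 and TNFRSF10B. Lists past camera, 5, numbered 8 without the filter, 0 with an estimated correlation and 5 to 7 with a library left out. Lists that passed only with a library left out or without the filter were mesenchymal and EMT markers (0.0344 without control 2), fatty acid synthesis (0.0177 without mimic 1), Wnt targets (0.0389 without mimic 1), MAPK genes (0.0227 without control 3), oxidative phosphorylation (0.000288 without mimic 2, 0.0189 without the filter), mitochondrially encoded genes (0.00705 without mimic 3, 0.0122 without control 1, 0.046 without the filter) and interferon genes (0.00334 without the filter). Terms, 5, numbered 31 in DESeq2 and 0 to 35 with a library left out. The seed site difference, -0.047, was -0.017 after correction for 3' UTR length, GC content and expression and -0.058 to -0.037 with a library left out. Beyond the settings said to test fewer libraries or other genes, the cause was not tested. At this depth and with 3 libraries per group, 46% of genes changed 1.3-fold were recovered in simulated data. Depth was not varied there, and genes of low mean count were not changed.

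With the replicate number as a block, 2162 genes were called (1079 higher, 1083 lower), 65 changed at least 2-fold, 30 terms passed, and FN1 passed at an adjusted p of 0.0454. ZNF625-ZNF20 lost its call in that fit. The deviations of libraries with the same number correlated at 0.12, 0.00 and 0.01, so the numbers were not taken to pair the samples. Such correlations over all genes are a weak check. A batch shared by mimic 1 and control 1 stays open. On the second principal component these lay at 19.4 and 25.6, apart from the other libraries. Mimic 2 correlated best with control 3, at 0.12.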

Other observations

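The tests of the complement strand, of G-rich sequence, of runs of G, of composition for genes with the complement strand's site, of coding sequences and of the extracellular matrix list were chosen only after the result was seen, and the other tests before.

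For genes lower with the mimic that carry the guide site, composition may account for most of the difference. After correction for 3' UTR length, GC content and expression, -0.017 of -0.047 (36.2%) was left. The bounds set beforehand were a percentile of at most 1 for the guide seed as cause and above 5 against it. The guide site's percentile among matched 7-mers was 6.71, so the test as written went against the guide seed. That percentile was not stable, at 1.55 to 19.02 with a library left out. It was 12.77 for 8mers alone, 1.93 for any site and 2.73 after correction. The guide site's corrected z of -3.07 ranked 66 of 16330. A small effect of the guide seed therefore stays open. Its corrected differences were not graded by site class (-0.015 for 8mers, -0.020 for 7mer-m8, 0.007 for 7mer-A1 and -0.015 for 6mers). Without the low-count filter the guide site's z was -0.82, at rank 2702 from the lowest. With a library left out its rank lay between 46 and 272. In the scan of 16330 7-mers after correction, the lowest z of all, -8.26, belonged to GGGGAGA. It is the site of bases 2 to 8 of the strand complementary to miR-1229-5p (its last 2 bases taken as an overhang). Along that strand, the site of bases 1 to 7 stood at -2.34. The sites of bases 3 to 9, 4 to 10 and 5 to 11 stood at -6.59, -7.22 and -5.96. All of these last sites hold GGGGG, so they do not separate a seed from runs of G. The reverse complement of GGGGAGA stood at -1.13. Corrected differences from genes with no site were -0.047 for 8mers, -0.042 for 7mer-m8, -0.013 for 7mer-A1 and 0.003 for 6mers. The tables argue against G-rich sequence as the whole cause. Among 7-mers of 5 G and 2 A, the 10 that share no 5-base stretch with the site had a median z of -2.11 (lowest -3.27). A part stays open, since that rule leaves out every 7-mer with GGGGA. The median of all 20 others was -2.53, and GGGGAAG stood at -4.93. The tables argue against runs of G as the whole cause too, since GGGGAGA stayed the lowest at -6.34 with the number of GGGG also corrected for. Here too a part stays open, with GGGGGAA at -5.25 and AGGGGGA at -4.78 before that step. They also argue against composition as the whole cause for these genes, since -0.044 of -0.070 was left after correction. A candidate explanation is that the complement strand of the mimic also acts on transcripts, STMN1 and CDH1 among those with its 8mer. SLC6A6 and DYNLL2 held its 7mer-m8 or 8mer too, while MMP14 and ITGA2 did not. Of 744 genes with its 8mer, 76 were called lower (10.2%) and 24 higher (3.2%), against 2.2% and 4.5% of genes without its site. Its 7mer-m8 or 8mer was in 36.5% of 449 lower genes searched and 11.6% of 551 higher genes, against 15.6% of all searched. For genes with its 7mer-m8 or 8mer, camera gave p = 0.000977, camera with an estimated correlation p = 0.0277 and fry p = 0.00791. That site was picked from the same fold changes, so these shares and p-values are no independent evidence. On the other side, TOMM22, called higher, has that 8mer too. Without the low-count filter GGGGAGA ranked 4 from the lowest with a z of -3.28. In coding sequences it ranked 1558 of 16384 (z -5.44). That scan was not corrected for the length or GC content of the coding sequences, so its rank decides nothing here. Whether the transfected duplex held the complement strand unmodified stays open, as does any change that miR-1229-5p makes without a seed site.

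Genes higher with the mimic were weighed as genes lowered by the control mimic, since each fold change compares the pair. The 7-mers CGGAGAA and TCGGAGA had the highest z after correction (7.59 and 7.24). This argues against 3' UTR length, GC content and expression as their whole cause. The correction did not take in CpG content, and both 7-mers hold CG, so it does not bear on that part of composition. Of 551 higher genes searched, 40 held TCGGAGA (7.3%), against 6 of 449 lower genes (1.3%) and 1.9% of all searched. Among the 20 of smallest p in each direction, 6 higher and 2 lower genes held it. TPM4 held the 8mer TCGGAGAA, ZCCHC3 the 7mer-A1 CGGAGAA and EMC6 only the 6mer, while TOMM22 and ZDHHC16 held none of these. On the other side, MMP14, called lower, held TCGGAGA. TCGGAGA ranked 1 of 16384 in coding sequences (z 6.22), where sites of the control mimic could also act. That scan was not corrected for the length or GC content of the coding sequences. The test set beforehand did not decide: the top z was 1.15 times the next independent 7-mer before correction and 1.88 times after it, the bounds had been set at 1.2 and 1.5, and the test had not named either scan. For genes with TCGGAGA, camera gave p = 1.16e-05, camera with an estimated correlation p = 0.0743 and fry p = 0.00723. Corrected differences from genes with no site were 0.181 for 8mers, 0.064 for 7mer-m8, 0.069 for 7mer-A1 and 0.026 for 6mers. Of 71 genes with the 8mer, 17 were called higher (23.9%) and 0 lower, against 3.7% and 3.4% of genes without a site. The 7-mer was picked from the same fold changes, so these values are no independent evidence. TCGGAGA ranked 47 without the low-count filter. TCGGAGA pairs with bases 2 to 8 of a common scrambled control that begins TTCTCCGA, a sequence recalled from general knowledge after the scan, and whether that control was used here is not known.

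For the lower extracellular matrix, protease and integrin list, the tables argue against direct sites of the complement strand as the whole cause: the 29 members without the 7-mer site had a median log2 fold change of -0.273, and the 16 without even a 6-mer site had one of -0.236, all 16 below 0. A part through 6-mer sites stays open, since 8 of the 14 members with one were called lower (median -0.364) and 3 of the 16 without. Over all genes searched, however, genes with only a 6mer of that strand differed by 0.003 after correction. Those with a 7mer-A1 differed by -0.013. A change that reaches these genes through another regulator, from either strand of the mimic or from the control mimic, may remain and was not tested. A response of the cells to miR-1229-5p itself, the difference the design names, stays open too.

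The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Every other split mixes mimic and control libraries on both sides. It therefore keeps part of the real contrast and adds the rest to the spread within a side. Its values are no reference for libraries without a difference. The real split gave 1081 called genes and the highest other split 3, and 41 genes changed at least 2-fold against 3, so 1 of 10 splits reached each count. It gave 11 called extracellular matrix genes against 0 and a seed site difference of 0.047 in size against 0.036, again 1 of 10 splits each, while the corrected z of TCGGAGA was 7.24 against 5.69 in another split (there the largest of all 7-mers) and that of GGGGAGA -8.26 against -4.87. For lists past camera it gave 5 against 13, and 6 of the 10 splits gave at least 5. The split with 13 set mimic 1, control 1 and control 2 apart, and on the second principal component (21.9% of the variance) mimic 1 and control 1 lay at 19.4 and 25.6 and the other libraries below 0, but the cause of the list count was not tested.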
